A study of Mus musculus with 122 samples.

How the data were processed

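The series holds RNA sequencing of mouse tissue lysates and of the matching TRAP fractions, in 122 libraries and 48 groups given by the labels. The deposited values are RPKM (reads normalised to transcript length and to mapped reads), in a joint table of all libraries and in 122 single-library tables that hold the same values. Per the submitters' processing notes, base calls were made with CASAVA 1.8.2 and reads were aligned with Bowtie2 2.2.3 to GRCm38.p2. The notes do not state the estimator of the RPKM or the gene model. The labels give 5 ng of cDNA for lysate libraries and 10 ng for TRAP libraries.

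Of 32810 gene IDs, 31825 matched GENCODE release M21, which gave symbols, positions and transcript lengths, and 985 did not. Short or ribosomal RNA IDs (5764), immune receptor segments (186) and matched IDs with transcripts under 200 nt (97) were left out with those not matched, which left 25778 testable IDs. From these the RNAs related to ribosomal RNA (mt-Rnr1, mt-Rnr2 and Gm42418) were also left out. There were 3 cells with a value of 1e+10, read as failed estimates, and genes with such a cell were left out. The depth was recovered from the smallest step between values of 3659 genes with a single transcript. With a tolerance of 0.15 step, 86.5% to 93.5% of low values fell on whole steps (median 90.5%). The lowest depth was that of blood lysate, 5.6 to 7.71 M reads, where a value of 1 RPKM rests on few reads per kilobase.

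The plan assumed counts. Because the values are RPKM, its fallback was used, limma 3.58.1 with a mean-variance trend on log2(RPKM + 1), in R 4.3.3 with data.table (version 1.17.8). Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Libraries of 1 fit were scaled by a trimmed mean of log ratios, with trims of 0.3 on ratios and 0.05 on means, and set to a median sum of 500000. Because of this scaling a log2 difference can depart from the ratio of the mean RPKM printed beside it, for example in heart, where lysate holds a mean of 49.0% mitochondrially encoded RNA and TRAP 2.54%. The added 1 makes the changes of low genes smaller than their ratios. A gene was tested when at least 3 libraries of the fit (2 for blood) had a scaled RPKM of 1 or more, and called at a Benjamini-Hochberg adjusted p under 0.05. The p-values measure the spread between these samples, and replicates are those the labels number.

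Tek-Cre and EIIa-Cre libraries of a tissue shared 1 fit of 12 libraries, as did control and LPS libraries and mechanical and enzymatic libraries. A gene was enriched beyond the pull-down control when Tek-Cre TRAP was above lysate and the Tek-Cre difference exceeded that of EIIa-Cre by over 1 log2 unit, both with adjusted p under 0.05. Of these, a gene was restricted to 1 bed when its TRAP was higher by over 1 log2 unit than in each of the other 4 tissues, with adjusted p under 0.05 for each. The response across 5 beds was tested with limma's F test on 4 degrees of freedom. Libraries without replicates were described by log2 ratios of genes with at least 100 estimated reads, and list medians were set against 10000 random lists matched in 20 expression bins.

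The comparisons, the thresholds, the rule for named genes and 33 gene lists were fixed before the data were examined. The rule took, per tissue, the 6 largest rises (and for LPS in TRAP the 4 largest falls) among genes without overlap between groups and with a mean log2 of at least 4 in the higher group for the main comparisons, the 3 largest rises and falls for the others, the 5 highest and 5 lowest ratios without replicates, and 2 to 4 members per list. A selection of these is printed. Predicted genes were counted and not named. The lists cover endothelium (pan-endothelial, blood-brain barrier, liver sinusoid, lung, heart and kidney endothelium), other cells (neurons, astrocytes and oligodendrocytes, cardiomyocytes, tubule, hepatocytes, lung epithelium, mural cells, fibroblasts, myeloid cells, lymphocytes, Kupffer cells, microglia, platelets and erythroid cells), responses (adhesion molecules, chemokines, NF-kB, interferon-stimulated, acute-phase, hemostasis, junction, VEGF and angiopoietin, immediate-early and heat-shock genes), mitochondrially encoded genes, nuclear noncoding RNAs and Y-linked genes. The last served as a label check, and Ddx3y was above Xist in 122 of 122 libraries of these male mice. Some genes sit in more than 1 list: Cldn5, Cdh5 and Esam (pan-endothelial and junction), Ocln (barrier and junction), Tie1, Tek, Kdr and Flt1 (pan-endothelial and VEGF), Vwf (pan-endothelial and hemostasis), Plat (kidney endothelium and hemostasis), F8 (sinusoid and hemostasis) and Fgb (hepatocytes and acute-phase).

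Alternatives planned for the 45 results were median-of-ratios scaling, no filter on low values, the replicate number as a block, leaving out each library, enrichment without the EIIa-Cre control, and a minimum of 500 estimated reads. A pseudocount of 0.1, no scaling between libraries and subtraction of tissue carry-over from TRAP were added after seeing the data. Carry-over was the level of the tissue's marker list in TRAP as a percent of its level in lysate. It was taken, and subtracted, on RPKM without scaling between libraries, so it also moves with the composition of the libraries. Whether replicate numbers pair libraries is not stated by any source used. It was checked by the correlation, across genes, of deviations from the group mean in lysate and TRAP of equal number, which was over 0.1 in every pair in 15 of 18 sets. In 50 of 54 pairs the deviations of a lysate were closest to those of the TRAP of its own number. The main fits took no account of such pairs, and counts with replicates as blocks are given where they moved. Replicates of a group had correlations of 0.805 to 0.991 across genes, which are not independent replicates. The calls were tested on simulated data with 200 changed genes per fit. All other genes had equal means in all groups, and libraries varied independently. In these data at most 0.141% of unchanged genes were called. Most real fits differed in far more genes and in composition, and lysate and TRAP of equal number were correlated. The simulated rates therefore hold for that setting only. A 2-fold change was called in 91% of genes for Tek-Cre TRAP against lysate in kidney, 22.4% in lung and 1.49% in blood.

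Scaling moved the median of all genes by over 0.1 in several comparisons. Without scaling it was 0.91 in heart (-0.04 with scaling), 0.39 in kidney (0.02), 0.70 in liver (0.12) and 0.22 in lung (-0.01) for Tek-Cre TRAP against lysate, and 0.64 in heart (0.01), 0.14 in kidney (-0.02) and -0.42 in lung (-0.11) for EIIa-Cre. For LPS in TRAP it was 0.35 in brain (0.17), -0.49 in heart (-0.01), -0.27 in kidney (0.01), -0.70 in liver (-0.12) and -0.71 in lung (-0.13), and in lysate -0.35 in heart (0.06), -0.31 in kidney (0.01), -0.40 in liver (-0.03) and -0.30 in lung (-0.05). For the interaction it was 0.38 in brain (0.15), -0.31 in liver (-0.13) and -0.47 in lung (-0.09), for enzymatic lysate -2.21 in brain (-0.42), -0.38 in kidney (-0.05) and -1.02 in liver (-0.06), and for blood 1.29 (0.07). With median-of-ratios factors the shift exceeded 0.1 for brain and liver in Tek-Cre (0.00 against -0.14, 0.00 against 0.12), lung in EIIa-Cre (0.02 against -0.11), brain and liver for LPS in TRAP (0.00 against 0.17, -0.01 against -0.12), brain and liver for the interaction (-0.02 against 0.15, 0.00 against -0.13) and brain for enzymatic lysate (-0.06 against -0.42).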

Results

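RNA was sequenced from whole-tissue lysates of mice and from the part of each lysate bound to tagged ribosomes, pulled down with an antibody against the tag (translating ribosome affinity purification, TRAP). The mice carried a floxed Rpl22 gene, in which Cre recombinase switches on a tagged ribosomal protein. Tek-Cre acts in endothelial cells and in much of the blood lineage, EIIa-Cre acts in most cells, and Pf4-Cre acts in megakaryocytes and platelets. The 122 libraries formed 48 groups, of which 36 held 3 libraries, 2 held 2 and 10 held 1. Lysate and TRAP of brain, heart, kidney, liver and lung came from male Tek-Cre mice aged 10 weeks, untreated or 4 hours after lipopolysaccharide (LPS, a bacterial cell wall component), and from EIIa-Cre mice. Brain, kidney and liver of Tek-Cre mice were also taken after enzymatic instead of mechanical dissociation. Blood after lysis of red cells gave 2 libraries per fraction. Transplant of Cre-negative bone marrow gave 1 library per fraction of brain, heart, kidney and liver, and pooled Pf4-Cre platelets gave 1 per fraction. The depth recovered from the deposited values was 5.6 to 30.8 M reads per library, with a median of 17.4 M reads. Changes are log2 differences from limma with their SE, levels are mean RPKM with their SD, and n is 3 per group unless another number is given. Counts for gene lists are over all genes tested, and the count adjusted over the list alone was equal wherever no second count is given.

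The first comparison set Tek-Cre TRAP against lysate, to ask which transcripts were enriched on endothelial ribosomes. In brain, 24 of 25 measured pan-endothelial genes were higher in TRAP, with a median log2 difference of 4.22. Pecam1, a junctional adhesion molecule of endothelium (GRCm38 chromosome 11, 106654217 to 106750628), had 4.72 ± 1.11 RPKM in brain lysate and 149 ± 5.09 RPKM in TRAP (SD, n = 3), a log2 difference of 4.70 ± 0.15. Plvap, a gene of fenestrated vessels, was the 1 member that was lower in brain TRAP, at -1.35 ± 0.25. All measured pan-endothelial genes were higher in TRAP of heart (24, median 1.85), kidney (25, median 3.88) and liver (24, median 3.35). In lung, 8 of 25 (11 adjusted over the list alone) were higher and none lower, with a median of 0.81, and 23 were higher with replicates as blocks (lysate and TRAP of equal number). Egfl7, a secreted endothelial factor, was higher in lung TRAP by 1.37 ± 0.32, and Pecam1 differed there by 0.81 ± 0.28 (adjusted p = 0.055 from limma, 0.00026 with replicates as blocks).

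Endothelial genes of single organs were enriched in the TRAP of their organ. In brain, 21 of 21 blood-brain barrier genes were higher (median 3.73), among them Slc2a1, the glucose transporter (chromosome 4, 119108711 to 119137983), with 38.4 ± 0.449 RPKM in lysate and 739 ± 195 RPKM in TRAP. In liver, 16 of 16 sinusoidal genes were higher (median 3.35), and Dnase1l3, a secreted DNase (chromosome 14, 7964533 to 7994573), went from 59.5 ± 5.81 to 3140 ± 937 RPKM. In heart, 12 of 13 heart-endothelium genes were higher (median 1.64), with Gpihbp1, the lipoprotein lipase anchor, up by 2.23 ± 0.11 and Timp4 by 2.48 ± 0.13. In kidney, 8 of 10 kidney-endothelium genes were higher and 2 lower (median 2.31), with Ehd3 higher by 4.15 ± 0.12 and Lpl lower at -1.70 ± 0.28. In lung, 4 of 13 lung-endothelium genes were higher (median 0.88, 11 with replicates as blocks), among them the carbonic anhydrase Car4 by 1.26 ± 0.30.

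Markers of the surrounding tissue were lower in TRAP. This held for 10 of 10 neuronal genes in brain (median -3.10), 12 of 12 astrocyte and oligodendrocyte genes in brain (median -3.25), 10 of 10 tubule genes in kidney (median -3.71) and 10 of 10 hepatocyte genes in liver (median -3.51). It also held for 9 of 10 epithelial genes in lung (median -4.85) and 8 of 10 (9 adjusted over the list alone) cardiomyocyte genes in heart (median -4.54). Sftpc, the surfactant gene of alveolar cells, went from 62900 ± 3070 RPKM in lung lysate to 1320 ± 117 RPKM in TRAP. The level of the tissue markers in control TRAP, as a mean percent of lysate, was 10.7% (SD 3.9) in brain, 13.9% (SD 14.7) in heart, 9.14% (SD 1.9) in kidney, 13.4% (SD 2.35) in liver and 4.13% (SD 0.566) in lung, and without TRAP replicate 3 the heart value was 5.42%. Mural cell genes were lower in brain (6 of 6), kidney (5 of 7, with 1 higher), liver (5 of 5) and lung (8 of 9), and fibroblast genes in brain (5 of 6), liver (6 of 6) and lung (7 of 7). In heart, 4 of 10 mural genes were lower, but their median of -0.14 became 0.64 without scaling between libraries. All measured mitochondrially encoded genes (9) were lower in each tissue, with medians from -4.78 in brain to -6.09 in heart. The nuclear noncoding RNAs such as Malat1 were lower in brain (6 of 6), heart (2 of 2), kidney (3 of 3), liver (2 of 2) and lung (3 of 3).

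Leukocyte and red cell genes were also higher in Tek-Cre TRAP. All 12 myeloid genes were higher in brain (median 4.62), heart (1.89), kidney (3.74) and liver (3.84), and 2 of 12 (3 adjusted over the list alone) in lung, where 8 were higher and 1 lower with replicates as blocks. Lyz2, the lysozyme of myeloid cells, had 30.1 ± 15 RPKM in brain lysate and 1170 ± 148 RPKM in TRAP. Lymphocyte genes were higher in brain (9 of 10), heart (6 of 8), kidney (11 of 11), liver (10 of 10) and lung (7 of 12, 8 adjusted over the list alone), with 11 in lung with replicates as blocks. All 8 microglial genes were higher in brain (median 5.04), with P2ry12, a purinergic receptor, at 1240 ± 387 RPKM in TRAP. All 7 genes of Kupffer cells, the resident macrophages of liver, were higher in liver (median 4.24), with the lectin Clec4f at 3390 ± 245 RPKM. Erythroid genes were higher in brain (6 of 6), heart (4 of 5, 5 adjusted over the list alone), kidney (5 of 6, with 1 lower) and liver (4 of 5, with 1 lower), and in lung none of 5 passed in limma (2 at an unadjusted p under 0.05) but 5 did with replicates as blocks. The globin genes among them are close paralogs, so their separate values are uncertain. Platelet genes were higher in brain (3 of 5, with 1 lower), heart (2 of 5), kidney (3 of 4), liver (4 of 4) and lung (2 of 9), with 4 in heart and 8 in lung with replicates as blocks.

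Over all genes, limma called 10729 of 13893 genes in brain (4737 higher in TRAP, 5992 lower), 6690 of 10603 in heart (3107 and 3583), 8615 of 11982 in kidney (4385 and 4230), 7646 of 10418 in liver (4264 and 3382) and 2661 of 11999 in lung (673 and 1988). With replicates as blocks the lung count was 5846, and without scaling between libraries it was 1497. The heart, with more genes lower than higher, turned the other way without scaling (8583 higher and 1386 lower).

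**Figure D1:**
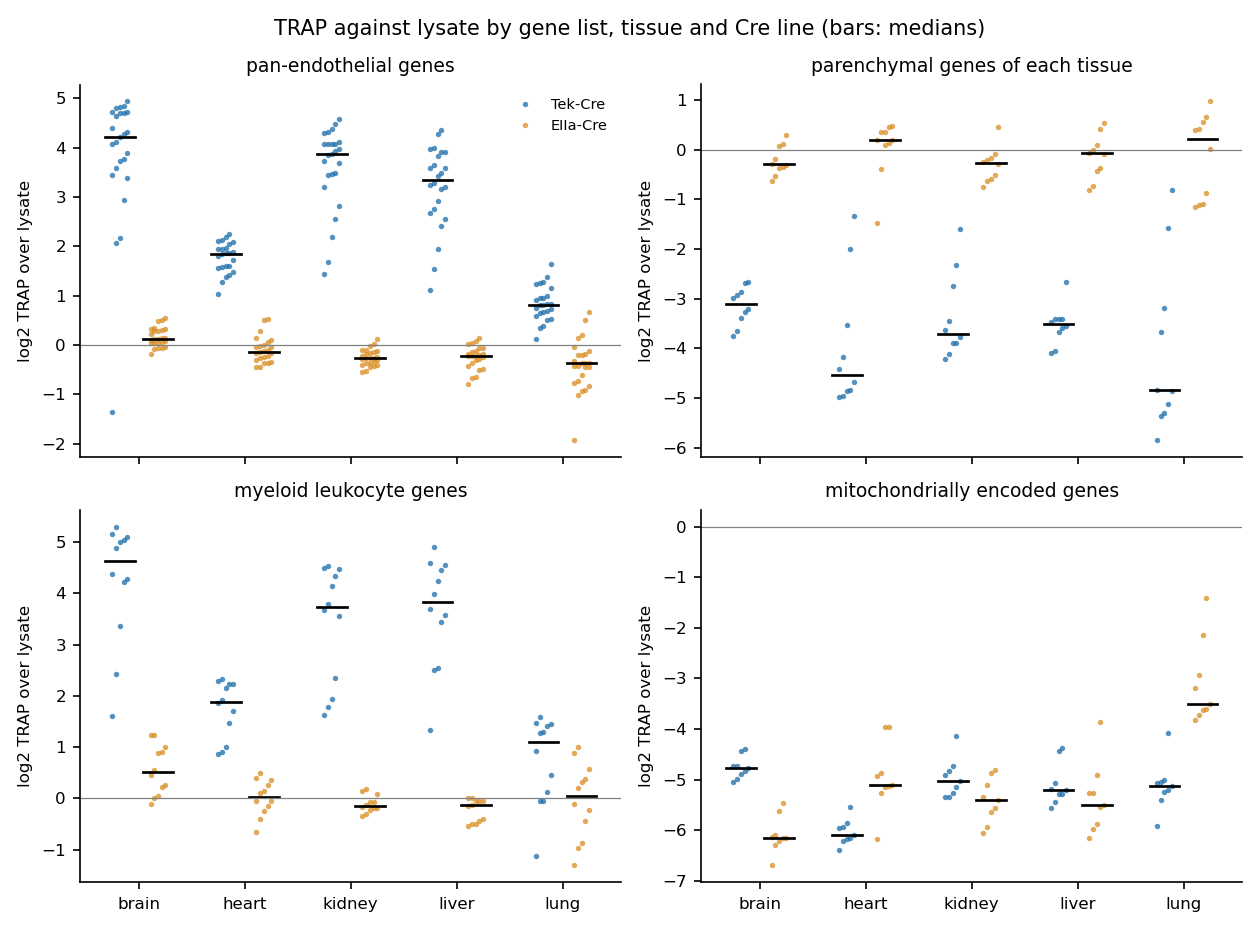
Each point is 1 gene, placed on the vertical axis by its log2 difference between TRAP and lysate (limma, 3 libraries per fraction), for the pan-endothelial, tissue-marker, myeloid and mitochondrially encoded lists in 5 tissues, with Tek-Cre in blue, EIIa-Cre in orange and bars at the medians. The Tek-Cre pan-endothelial medians stand at 4.22, 1.85, 3.88, 3.35 and 0.81 in brain, heart, kidney, liver and lung, and the mitochondrial medians in brain at -4.78 for Tek-Cre and -6.15 for EIIa-Cre.

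The EIIa-Cre mice, in which most cells carry the tag, served as the control for what the pull-down itself does. Few pan-endothelial genes passed the test there. In brain none of 25 was called by limma (median 0.12, 3 higher at an unadjusted p under 0.05). In the other tissues the genes called were Ramp2 (0.52 ± 0.14) and Ptprb (-0.31 ± 0.09) in heart (none adjusted over the list alone), 1 of 25 (3 adjusted over the list alone) lower in kidney (Ptprb, -0.55 ± 0.12), 3 of 24 (4 adjusted over the list alone) lower in liver (Cdh5, Kdr and Ptprb) and 4 of 25 lower in lung (Cdh5, Ptprb, S1pr1 and Myct1), named after their values were seen. With replicates as blocks, Ramp2 was called in brain (not adjusted over the list alone), Ptprb in heart was not (adjusted p = 0.0664 from limma), 3 (6 adjusted over the list alone) were lower in kidney, and in lung 13 (14 adjusted over the list alone) were lower and 2 higher. Mitochondrially encoded genes were lower in brain (9 of 9, median -6.15), heart (9 of 9, -5.10), kidney (9 of 9, -5.41), liver (9 of 9, -5.51) and lung (8 of 9, 9 adjusted over the list alone, -3.50), and the nuclear noncoding RNAs were lower in brain (6 of 6) and lung (3 of 3). The tissue markers stood at 91.8% (SD 12.8) of lysate in brain, 210% (SD 4.34) in heart, 95.8% (SD 13.6) in kidney, 96.4% (SD 8.59) in liver and 77.7% (SD 59.5) in lung, the last at 51.3% without TRAP replicate 2. These percents are of RPKM without scaling, and in heart mitochondrially encoded RNA took a mean of 52.1% of lysate and 4.13% of TRAP. Mrfap1 was higher in TRAP of brain by 1.62 ± 0.10 and of heart by 1.57 ± 0.17. The lung libraries of this line carried a mean of 28.1% (lysate) and 22.7% (TRAP) of their RPKM in RNA related to ribosomal RNA, against 5.22% and 3.43% for Tek-Cre lung.

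For EIIa-Cre, limma called 2136 genes in brain (1099 higher in TRAP, 1037 lower), 1373 in heart (785 and 588), 207 in kidney (78 and 129), 513 in liver (295 and 218) and 1246 in lung (395 and 851). These counts moved by over 1.5 times without brain TRAP replicate 1 (1251), brain TRAP replicate 3 (1404), brain lysate replicate 1 (1399), lung TRAP replicate 3 (703), lung lysate replicate 2 (825), lung lysate replicate 3 (215), any 1 of the heart libraries but lysate replicate 1 (570, 641 and 736 without TRAP replicates 1, 2 and 3, 678 and 744 without lysate replicates 2 and 3), any 1 kidney library (106, 68 and 90 without TRAP replicates 1, 2 and 3, 87, 69 and 78 without lysate replicates 1, 2 and 3) or any 1 liver library (127, 100 and 121 without TRAP replicates 1, 2 and 3, 162, 125 and 231 without lysate replicates 1, 2 and 3). With replicates as blocks the counts were 646 in kidney, 1033 in liver and 5225 in lung, and without scaling they were 8229 in heart (8144 higher and 85 lower), 1299 in kidney and 72 in lung.

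Genes enriched beyond the pull-down control were those with a Tek-Cre enrichment over 1 log2 unit above that of EIIa-Cre. There were 2567 such genes in brain, 1092 in heart, 2425 in kidney, 2538 in liver and 79 in lung. They held 24, 23, 25, 24 and 3 of the pan-endothelial genes in these tissues (16 in lung with replicates as blocks). They also held all 12 myeloid genes in brain, heart, kidney and liver, 8 of 8 microglial genes in brain and 7 of 7 Kupffer cell genes in liver. By size, the named genes included the organic anion transporter Slco1a4 in brain (4.82 ± 0.25, 13.8 and 338 RPKM in lysate and TRAP), Icam2 in heart (2.23 ± 0.16) and kidney (4.83 ± 0.24), Egfl7 in kidney (4.80 ± 0.24), Dnase1l3 in liver (5.23 ± 0.28) and Fibin in lung (2.06 ± 0.49). They also included H2-Ab1, an antigen-presentation gene, in brain (5.05 ± 0.42) and liver (5.14 ± 0.42), the complement gene C1qc in kidney (5.17 ± 0.26) and liver (5.04 ± 0.26), and the B-cell gene Cd79b in lung (1.98 ± 0.50). Of 8778 genes tested in 5 tissues, 29 were enriched in all 5 (0.0698 if independent) and 566 in 4 (13.2 if independent). The liver count was 1640 without TRAP replicate 1 and 1680 without TRAP replicate 3, and without scaling it was 4583 in liver and 2474 in heart. The lung count was 423 with replicates as blocks, 135 with median-of-ratios factors, 5 without scaling, 161 without EIIa-Cre TRAP replicate 2, 35 without EIIa-Cre lysate replicate 3, 51 and 33 without Tek-Cre TRAP replicates 2 and 3, and 43 and 16 without Tek-Cre lysate replicates 1 and 3.

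Enriched genes were next compared between vascular beds, to find those higher in the TRAP of 1 tissue than in each of the other 4. There were 267 in brain, 45 in heart, 72 in kidney, 200 in liver and 21 in lung, among 13579 genes tested by limma. The brain set held 20 of 21 blood-brain barrier genes, led by Slco1c1, a thyroid hormone transporter (207 RPKM in brain TRAP, at least 7.09 ± 0.14 log2 units above each other bed). It also held 4 of 8 microglial genes, with P2ry12 at 6.09 ± 0.29 and 1240 ± 387 RPKM, and 3 of 12 myeloid genes, and the crystallin gene Crybb1 stood at 6.53 ± 0.28. The liver set held 14 of 16 sinusoidal genes, such as the lectin Clec4g (8.29 ± 0.19), and 6 of 7 Kupffer cell genes, such as Clec4f (9.03 ± 0.33). The heart set held 6 of 13 heart-endothelium genes, with the transcription factor Meox2 at 3.66 ± 0.28, and the kidney set 6 of 10 kidney-endothelium genes, with the Wnt antagonist Dkk2 at 3.93 ± 0.18. The lung set held 0 of 13 lung-endothelium genes (6 with replicates as blocks) and was led by Krt79, a keratin (4.89 ± 0.20). The kidney count was 43 and 47 without kidney TRAP replicates 1 and 3, the liver count 131 without liver TRAP replicate 1, and the lung count 13 and 9 without lung TRAP replicates 1 and 3. With replicates as blocks the lung count was 103. With the EIIa-Cre criterion left out it was 67, and without scaling the heart and lung counts were 76 and 1.

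LPS was then compared with control in TRAP, to ask how the endothelial transcripts of each organ respond to endotoxin. Chemokine and cytokine genes rose in brain (14 of 14, median 2.73), heart (14 of 14, 6.56), kidney (14 of 14, 4.70), liver (13 of 13, 5.41) and lung (13 of 14, 5.48). Cxcl10, a T-cell chemokine (chromosome 5, 92346638 to 92348889), rose by 7.55 ± 0.22 in brain (from 4.62 ± 2.22 to 1180 ± 144 RPKM), 9.86 ± 0.22 in heart, 8.23 ± 0.21 in kidney and 10.57 ± 0.43 in lung. Interferon-stimulated genes rose in brain (16 of 18, median 2.22, with 1 lower), heart (18 of 18, 5.00), kidney (18 of 18, 3.44), liver (18 of 18, 4.74) and lung (18 of 18, 4.19), with Rsad2, an antiviral enzyme, up by 8.50 ± 0.27 in lung. Acute-phase genes rose in brain (9 of 9), heart (8 of 9), kidney (9 of 9), liver (10 of 10) and lung (8 of 8), with Saa3 up by 11.47 ± 0.38 in liver and 12.85 ± 0.30 in lung, where the close paralogs of this family leave the single-gene values uncertain. The selectin gene Selp rose by 3.54, 6.69, 4.29, 2.70 and 3.63 in brain, heart, kidney, liver and lung, within leukocyte adhesion counts of 3 of 4, 4 of 4, 4 of 4, 3 of 4 and 3 of 4. Of 9233 genes tested in all 5 tissues, 179 were at least 2-fold higher in TRAP of each (0.822 if independent).

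Pan-endothelial genes fell in TRAP after LPS. The fall covered 24 of 25 in brain (median -3.29, with 1 higher), 17 of 24 in heart (-1.01, 2 higher), 23 of 25 in kidney (-3.11), 23 of 24 in liver (-3.41) and 19 of 25 (20 adjusted over the list alone) in lung (-1.37, 2 higher). Robo4, an endothelial guidance receptor, rose in heart (0.92 ± 0.21) and lung (1.56 ± 0.20), and Plvap rose in brain (1.02 ± 0.13). Genes of single organs fell as well, in 20 of 21 blood-brain barrier members in brain (median -3.11), 15 of 16 sinusoidal members in liver (-3.12), 10 of 13 in heart (-1.39), 11 of 13 in lung (-2.05) and 6 of 10 in kidney (-0.44). Slc2a1 in brain fell by 2.83 ± 0.16, from 739 ± 195 to 117 ± 22.7 RPKM, Clec4g in liver by 5.55 ± 0.49 and the prostaglandin-degrading enzyme Hpgd in lung by 4.76 ± 0.39. Among the largest falls were Degs2 in brain (-5.59 ± 0.20), the glycerol channel Aqp7 in heart (-4.54 ± 0.18), Tmem204 in kidney (-5.77 ± 0.21) and liver (-6.33 ± 0.24) and Mfap2 in lung (-5.82 ± 0.44).

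Markers of other cells moved beside these groups in LPS TRAP. The tissue markers rose in brain (10 of 10 neuronal genes, median 2.30, and 10 of 12 astrocyte and oligodendrocyte genes, 1.91), kidney (9 of 10, 1.95), liver (10 of 10, 1.99, a list that shares Fgb with the acute-phase genes) and heart (5 of 10, 1.84). Their level in LPS TRAP was 71.8% (SD 8.37) of lysate in brain, 38.2% (SD 20.1) in heart, 48.8% (SD 7.86) in kidney, 60.5% (SD 12.6) in liver and 2.42% (SD 0.368) in lung. These percents are of RPKM without scaling. In the scaled fits the median fold of TRAP over lysate after LPS was 0.627 in brain, 0.175 in heart, 0.421 in kidney and 0.401 in liver. After subtraction of the carry-over taken without scaling, an alternative chosen after seeing the data, the pan-endothelial fall covered 25 of 25 members in brain (median -3.01), 22 of 25 in kidney (-2.69) and 23 of 24 in liver (-3.49), and 9, 6 and 8 of 12 myeloid genes were lower (0, 2 and 2 higher). The subtraction was partial, since the tissue-marker medians of these tissues remained at 1.12, 1.02 and 0.76. Mitochondrially encoded genes rose in brain (9 of 9), heart (9 of 9), kidney (9 of 9) and liver (9 of 9), and in lung 2 of 9 (0 adjusted over the list alone) fell. Myeloid genes fell in brain (10 of 12), kidney (8 of 12, 2 higher) and liver (10 of 12, 2 higher), and lymphocyte genes in brain (10 of 10), heart (5 of 8), kidney (11 of 11), liver (10 of 10) and lung (9 of 12, 10 adjusted over the list alone). In lung 6 of 12 myeloid genes rose and none fell, and in heart 5 (6 adjusted over the list alone) rose and 4 fell, with a median of 0.26 that became -0.22 without scaling. All 8 microglial genes fell in brain (median -2.59) and all 7 Kupffer cell genes in liver (median -3.81).

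Over all genes, limma called 10947 of 14157 in brain TRAP (6172 higher after LPS, 4775 lower), 6672 of 11015 in heart (3254 and 3418), 8727 of 12299 in kidney (4418 and 4309), 8023 of 10911 in liver (3652 and 4371) and 6485 of 11972 in lung (2819 and 3666). Among the largest rises in brain were Prrc2c (6.93 ± 0.27) and Dlat (6.56 ± 0.30), and in lysate Dlat differed by 0.07. Without scaling, falls outnumbered rises in kidney as well (3674 higher and 5760 lower).

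**Figure D2:**
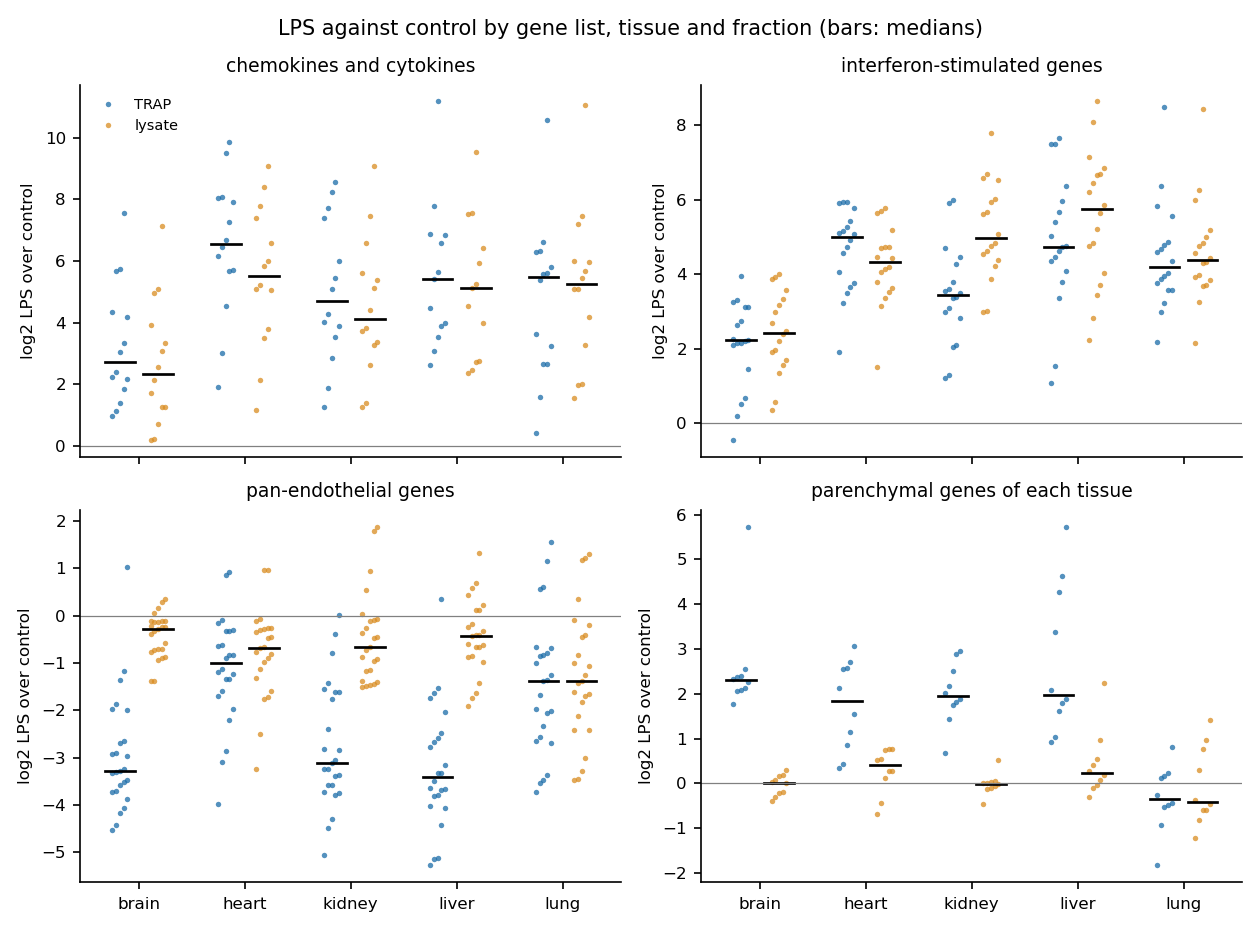
Each point is 1 gene, placed on the vertical axis by its log2 difference between LPS and control (limma, 3 libraries per group), for the chemokine, interferon-stimulated, pan-endothelial and tissue-marker lists in 5 tissues, with TRAP in blue, lysate in orange and bars at the medians. The pan-endothelial medians lie at -3.29 in TRAP and -0.29 in lysate of brain, and at -1.37 and -1.39 in lung.

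**Figure D3:**
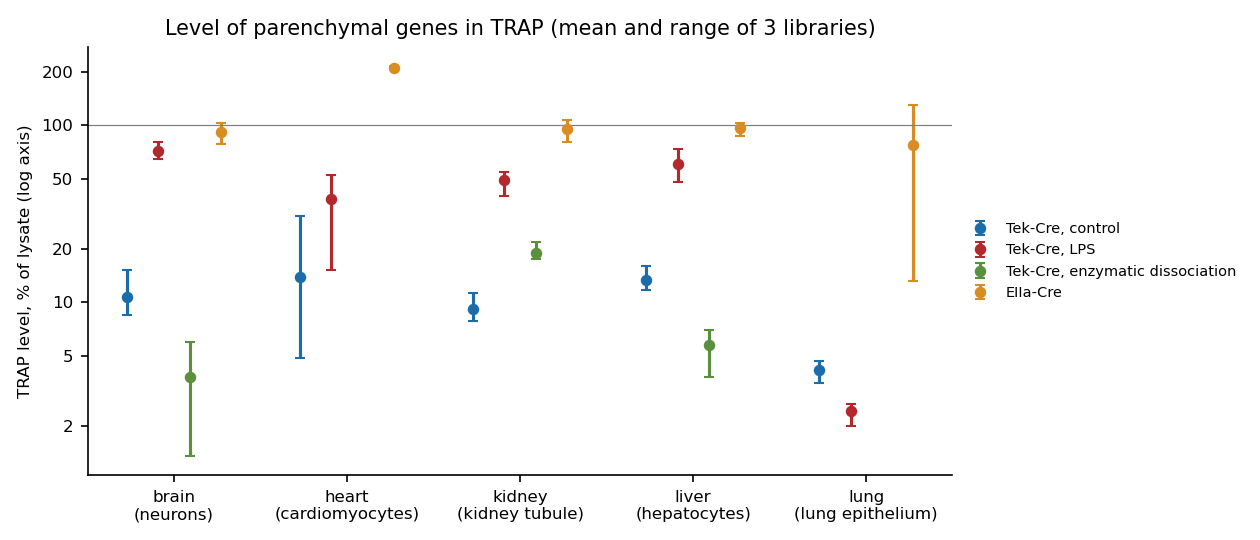
The vertical axis (log scale) gives the level of the tissue-marker list in TRAP as a percent of its level in lysate (RPKM without scaling between libraries), with points at the mean and bars over the range of 3 libraries, for control, LPS, enzymatic and EIIa-Cre groups in 5 tissues. The brain values are 10.7% in control, 71.8% after LPS and 91.8% in EIIa-Cre, and the lung values 4.13%, 2.42% and 77.7%.

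The lysates gave the response of the whole tissue to LPS. Chemokine genes rose in brain (12 of 14), heart (14 of 14), kidney (14 of 14), liver (13 of 13) and lung (14 of 14), and interferon-stimulated genes in 17 of 18 (18 adjusted over the list alone) members in brain and all 18 in each other tissue. Cxcl10 rose by 7.15 ± 0.22 in brain and 11.05 ± 0.43 in lung. Acute-phase genes rose in brain (8 of 9, 9 adjusted over the list alone), heart (6 of 9), kidney (7 of 9), liver (10 of 10) and lung (7 of 8). All 4 leukocyte adhesion genes rose in brain, heart, kidney and liver, and 3 of 4 in lung. Pan-endothelial genes fell in brain (9 of 25, 10 adjusted over the list alone, median -0.29), heart (13 of 24, -0.67), kidney (13 of 25, 15 adjusted over the list alone, -0.66), liver (10 of 24, 11 adjusted over the list alone, -0.42) and lung (16 of 25, -1.39), with Egfl7 in heart at -3.24 ± 0.19. Among the largest falls were the glucose-6-phosphatase gene G6pc in liver (-4.75 ± 0.27), the desaturase Scd1 in heart (-4.61 ± 0.48), and Cx3cr1 (-1.99 ± 0.30) and P2ry12 (-1.49 ± 0.32) in brain. In lung, 8 of 9 mitochondrially encoded genes fell (median -1.79).

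In lysate, limma called 2404 genes in brain (1366 higher, 1038 lower), 3657 in heart (2183 and 1474), 3358 in kidney (1999 and 1359), 4142 in liver (2156 and 1986) and 5021 in lung (2463 and 2558). The brain count was 1474 and 1272 without control lysate replicates 1 and 3 and 1326 without LPS lysate replicate 2. Without scaling, falls outnumbered rises in brain (1045 higher and 1480 lower), heart (781 higher and 4281 lower), kidney (1058 higher and 4222 lower) and liver (1158 higher and 4758 lower).

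The difference between these responses was tested as the interaction of LPS and fraction. Pan-endothelial genes fell more in TRAP than in lysate in brain (24 of 25, median -2.96), kidney (25 of 25, -2.35) and liver (24 of 24, -2.86), but in heart 1 of 24 passed (Clec14a, -1.14 ± 0.19, chosen after its value was seen) and in lung none of 25 passed in limma (median -0.27, 1 lower at an unadjusted p under 0.05). With replicates as blocks 2 (1 adjusted over the list alone) were lower in heart, and in lung 4 (3 adjusted over the list alone) were lower and 1 higher. Of simulated 2-fold interactions 19.4% were called in lung, so a difference of that size may have been missed there. Neuronal (10 of 10), tubule (9 of 10) and hepatocyte (10 of 10) genes rose more in TRAP than in lysate. Myeloid genes fell more in TRAP of brain (11 of 12), kidney (11 of 12, 12 adjusted over the list alone) and liver (12 of 12). Over all genes the interaction was called for 9655 in brain (5364 higher in TRAP, 4291 lower), 2175 in heart (860 and 1315), 6647 in kidney (3072 and 3575), 6223 in liver (2580 and 3643) and 255 in lung (67 and 188). The lung count was 2866 with replicates as blocks and 1534 without scaling, and leaving out any 1 library but LPS lysate replicate 3 moved it. It was 97, 159 and 66 without control TRAP replicates 1, 2 and 3, 104, 88 and 72 without control lysate replicates 1, 2 and 3, 138, 164 and 385 without LPS TRAP replicates 1, 2 and 3, and 96 and 162 without LPS lysate replicates 1 and 2. The heart count was 1444 without LPS lysate replicate 3 and 3328 with carry-over subtracted, and its split turned to 1190 higher and 964 lower with median-of-ratios factors.

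Whether the LPS response in TRAP differed between the 5 vascular beds was tested with limma's F test. It differed for 13876 of 15496 genes. By the calls of each tissue's own fit, 1330 genes were at least 2-fold higher in 1 bed and 2-fold lower in another. The tissue markers in TRAP also moved differently. They went from 10.7% to 71.8% of lysate in brain, 13.9% to 38.2% in heart, 9.14% to 48.8% in kidney, 13.4% to 60.5% in liver and 4.13% to 2.42% in lung. How much of the difference between beds comes with this was not tested. The chemokine gene Ccl2 rose by 3.34 in brain and 8.06 in heart, and the interleukin gene Il6 by 1.86 and 6.45. The metallothionein gene Mt2 rose by 5.14 in brain, 8.77 in heart and 9.07 in lung.

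Enzymatic dissociation was compared with mechanical dissociation in brain, kidney and liver, to ask what digestion of the tissue does to the profile. The brain and liver libraries differed in composition. RNA related to ribosomal RNA took a mean of 88.4% of RPKM in enzymatic brain lysate and 77.2% in TRAP, against 3.93% and 1.2% after mechanical dissociation. In liver it took 60.7% and 41.6%, against 2.77% and 0.57%, and in kidney 11.4% and 4.19%, against 3.37% and 0.66%. Enzymatic brain TRAP had 4258 to 5180 genes over 1 RPKM, against 11786 to 12289. The median of all genes in TRAP shifted by -1.17 in brain and -0.52 in liver, and by -2.12 and -1.49 without scaling. With median-of-ratios factors these shifts were -0.32 and -0.14. Kidney shifted by 0.06 (-0.09 without scaling).

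In kidney TRAP, 14 of 25 (15 adjusted over the list alone) pan-endothelial genes rose with enzymatic dissociation and 1 fell (median 0.60), with the tight-junction gene Cldn5 going from 20.5 ± 8.48 to 118 ± 19.5 RPKM. Beside them, 8 of 10 tubule genes and 9 of 9 mitochondrially encoded genes rose, and the tubule markers stood at 19% (SD 2.44) of lysate. In liver TRAP, 17 of 25 pan-endothelial genes fell and 0 (1 adjusted over the list alone) rose (median -1.18), Dnase1l3 fell by 6.14 ± 0.34, and 8 of 12 myeloid genes rose with 1 lower, a list whose median of 1.15 became -0.11 without scaling. The neutrophil gene S100a9 rose in liver TRAP by 5.81 ± 0.34. In brain TRAP, 6 pan-endothelial genes rose and 8 of 25 fell, and their median of -0.44 became 1.07 with median-of-ratios factors. Neuronal genes fell there in 7 of 10 members (median -2.46), while 3 of 4 tubule genes (2.36) and 5 of 7 hepatocyte genes (1.40, which became -0.47 without scaling) rose. In lysate, pan-endothelial genes rose in liver (18 of 25, 20 adjusted over the list alone, median 1.49) and in brain (18 of 25, 1 lower, median 1.71, which became -0.40 without scaling), and in kidney 3 (1 adjusted over the list alone) rose and 4 (3 adjusted over the list alone) fell. Beside them, 12 of 12 myeloid (median 3.03) and 7 of 7 Kupffer cell genes (2.33) rose in liver, and 7 of 7 fibroblast genes fell in kidney (-1.54). In brain lysate, mural (6 of 8, 7 and 1 lower adjusted over the list alone, median 1.35), microglial (6 of 8, 1.70), hepatocyte (6 of 7, 1 lower, 2.10) and tubule genes (3 of 4, 2.66) rose, and the medians of the first 3 became -0.95, -1.36 and -0.01 without scaling. Cfd, an adipocyte gene, fell in kidney TRAP from 1300 ± 774 to 2.71 ± 0.565 RPKM.

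In TRAP, limma called 9406 genes in brain (1036 higher after enzymatic dissociation, 8370 lower), 5575 in kidney (3193 and 2382) and 5256 in liver (1181 and 4075), and in lysate 6963 (2254 and 4709), 4749 (2138 and 2611) and 4118 (1909 and 2209). Without scaling the counts were 9099 in liver TRAP, 12632 in brain lysate and 7178 in liver lysate, and the kidney TRAP split turned to 2358 higher and 3426 lower. With median-of-ratios factors the brain lysate split turned to 2710 higher and 2650 lower.

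In blood, TRAP was compared with lysate after lysis of red cells (n = 2 per fraction), since Tek-Cre also tags blood cells. Erythroid genes were lower in TRAP (7 of 7, median -3.67), with Hbb-bs, an adult beta globin, at 355000 ± 7270 RPKM in lysate and 48600 ± 18300 in TRAP. Mitochondrially encoded genes were lower too (8 of 9, 9 adjusted over the list alone, median -3.63), and lymphocyte genes gave 0 of 12 (3 adjusted over the list alone) higher in limma (median 0.48, 3 at an unadjusted p under 0.05), and 3 (4 adjusted over the list alone) with replicates as blocks. Arpp19, a phosphatase regulator, was higher in TRAP (59.1 ± 0.296 RPKM in lysate and 1020 ± 134 in TRAP, adjusted p = 0.0045 from limma). In all, 145 of 7399 genes were called (23 higher, 122 lower), and 83 and 93 without TRAP replicates 1 and 2. With replicates as blocks the count was 598. The split turned without scaling (4282 higher and 59 lower), and 1 gene was called without the filter on low values.

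Tek-Cre tissue after transplant of Cre-negative bone marrow was set beside control Tek-Cre tissue, to see which enriched transcripts come with tagged blood cells. There was 1 such library per tissue and fraction, so no test was run, and these libraries stood apart from control. RNA related to ribosomal RNA took 0.02% (brain) to 0.16% (liver) of RPKM in TRAP, against 0.57% (liver) to 1.44% (heart) in control, and mitochondrially encoded RNA 9.84% against 16.5% in brain lysate and 34.8% against 49.0% in heart lysate. The log2 ratio of TRAP over lysate differed from control by a median over members of 0.77 for neuronal, 0.23 for cardiomyocyte, 0.73 for tubule and 1.06 for hepatocyte genes, and of 1.18 for mitochondrially encoded genes in liver. The median pan-endothelial log2 ratio of TRAP over lysate was 4.61 in brain (control 4.30), 2.18 in heart (2.07), 4.35 in kidney (4.02) and 3.48 in liver (3.48). The erythroid median was -1.17 in brain (control 5.09), -3.60 in heart (2.47), -1.99 in kidney (4.46) and -1.91 in liver (4.55). The myeloid median was -0.81 in heart (2.25) and 0.92 in kidney (4.29), but 4.86 in brain (5.02), where microglia reside, and 3.13 in liver (4.38). Ratios in brain were highest for Depp1 (6.40), Ctla2a (6.11) and Ly6c1 (6.03).

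**Figure D4:**
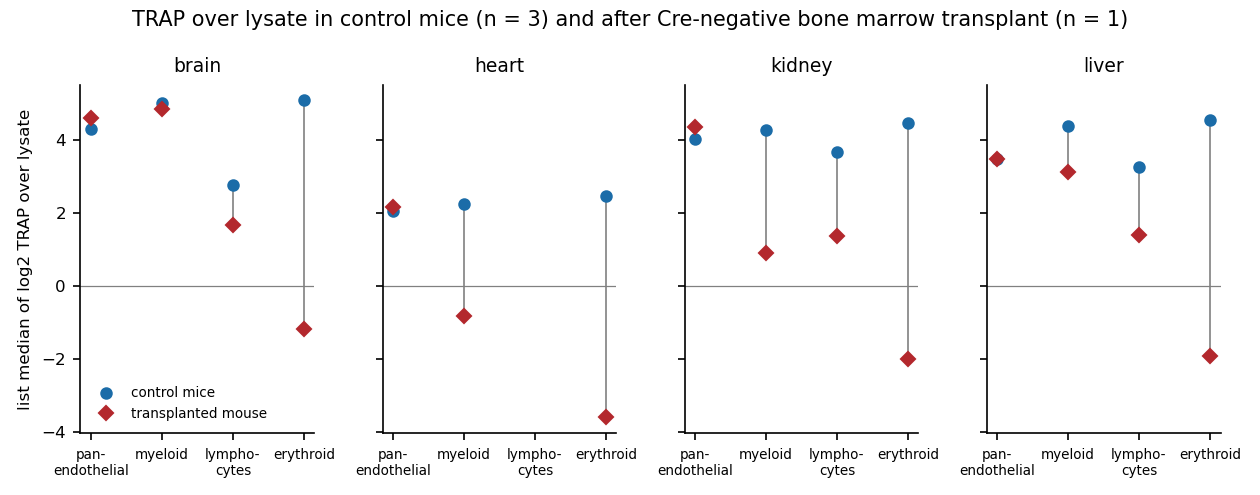
The vertical axis gives the list median of the log2 ratio of TRAP over lysate, for pan-endothelial, myeloid, lymphocyte and erythroid genes in brain, heart, kidney and liver, with circles for control mice (3 libraries per fraction) and diamonds for Cre-negative marrow (1 library per fraction), and no lymphocyte value in heart. The erythroid medians drop from 5.09 to -1.17 in brain, while the pan-endothelial medians of brain are 4.30 and 4.61.

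Pooled Pf4-Cre platelets gave the TRAP profile of platelets themselves, from 1 library per fraction and so without a test. Platelet genes had a median log2 ratio of 0.28, with 9 of 12 higher in TRAP, among them Tubb1, the platelet tubulin (0.65), and the integrin Itga2b (0.28). This median was at percentile 91.3 of random lists matched on level, and some lists of other cells stood higher, at 0.36 for 6 pan-endothelial, 0.40 for 3 sinusoidal, 0.54 for 3 astrocyte and oligodendrocyte and 0.55 for 3 junction genes. The median was -3.52 for 7 erythroid genes, -3.65 for 5 lymphocyte genes and -5.70 for 9 mitochondrially encoded genes. Ratios were highest for Gnb2 (2.00) and Mtmr14 (1.82).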

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

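Tests in this part chosen only after the result was seen are those of carried-over tissue RNA, those of lower endothelial abundance, those of the erythroid list and those against the SD between control replicates, while those of transcript length and GC content, of the myeloid and lymphocyte lists and of other splits of the libraries were chosen before.

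The response to LPS differed between tissues and between fractions. Limma's F test called 13876 genes whose LPS change in TRAP differed across the 5 tissues. By the calls of each tissue's own fit, 1330 genes were 2-fold higher in 1 tissue and 2-fold lower in another. The LPS change differed between TRAP and lysate for 9655 genes in brain, 2175 in heart, 6647 in kidney, 6223 in liver and 255 in lung.

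The first pattern weighed is the fall of endothelial and leukocyte lists in LPS TRAP of brain, kidney and liver. More tissue RNA carried into LPS TRAP stays open as a part of it, and 29 of 30 neuron, tubule and hepatocyte genes rose in TRAP against lysate after LPS. This rise does not decide, since RPKM are shares of a library and cannot tell more carried-over RNA from less tagged RNA. Carried-over RNA as the whole cause of the pan-endothelial fall is argued against by lysate, which it cannot change and where 32 of 74 pan-endothelial members of the 3 tissues also fell. Subtraction of the carry-over left TRAP medians of -3.01, -2.69 and -3.49 in brain, kidney and liver, against -3.29, -3.11 and -3.41 before it. These medians do not decide, since subtracting a share of lysate takes little from genes that are low in lysate. It also left part of the marker rise, with medians of 1.12 for neuronal, 1.02 for tubule and 0.76 for hepatocyte genes. Lower abundance of endothelial transcripts after LPS remains open for a part. The lysate median of the list was -0.29 in brain, -0.66 in kidney and -0.42 in liver. Each lay below 0 by more than its standard error over genes (0.09, 0.19 and 0.16). That error takes the members of a list as independent and does not measure the spread between mice, so it does not decide. The fall in TRAP was larger by a difference that passed the test for 24 of 25, 25 of 25 and 24 of 24 members. What accounts for the part that neither carry-over nor the fall in lysate covers was not tested. For the leukocyte lists no value decided, since in lysate 1, 1 and 2 (3 adjusted over the list alone) of 12 myeloid genes fell and 1, 4 and 4 rose in brain, kidney and liver (in liver with a median of -0.11 and a mean of 0.87), and with carry-over subtracted 9, 6 and 8 of 12 were lower in TRAP (medians -1.62, -0.63 and -2.51).

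The second pattern is a set of 82 genes, Dlat among them, over 8-fold higher in LPS TRAP of brain with little change in lysate. In LPS TRAP, 57.3% of the genes lay above lysate by over 1 log2 unit (53.7% with median-of-ratios factors, 68.3% without scaling). A share of lysate cannot reach this level, which argues against carried-over tissue RNA as the cause for these genes. It stays open for the other genes. The share itself is partly set by the choice of genes. A rise over 8-fold from a median control log2 ratio of -2.17 puts many above lysate, and the medians in kidney and liver were -3.39 and -3.18. Sets chosen in the same way in kidney (57 genes) and liver (49 genes) had 22.8% and 16.3% above lysate by that much, with median log2 ratios to lysate of -0.35 and 0.11, and were not weighed. The length of the transcript stays open, with a median of 4180 nt at percentile 100 of 10000 random sets matched on level. GC content stays open at percentile 97.5, at the border of the random sets. The random sets were not matched on the ratio to lysate in control TRAP or on the cell type of the genes, so these percentiles do not decide. No biological explanation was tested.

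The third pattern is the enrichment of leukocyte and erythroid lists in Tek-Cre TRAP. Tagged erythroid cells from Tek-Cre marrow are a candidate source, since the erythroid list was lower by over 1 log2 unit with Cre-negative marrow in 4 of 4 tissues. For tagged blood cells as the source of the myeloid and lymphocyte lists, 7 of the planned 8 pairs of list and tissue could be measured (lymphocytes in heart could not). By the median difference of members, 5 were lower by over 1, 1 short of the number set beforehand. By the list medians themselves, liver myeloid genes (3.13 against 4.38 in control) were lower by over 1 as well, which reaches that number. The outcome turns on which median is taken, so with 1 library per tissue and fraction that explanation cannot be told apart from others. Capture of untagged blood-cell RNA by the pull-down is argued against for the erythroid list, lower by over 1 plus the SD between control replicates in 4 of 4 tissues, and as the whole source of the myeloid and lymphocyte lists, where this held for 4 of the 7 pairs (myeloid -2.71 in heart and -2.95 in kidney, lymphocytes -2.64 in kidney and -1.82 in liver), while untagged tissue markers were not lower (neurons 0.77, cardiomyocytes 0.23, tubule 0.73, hepatocytes 1.06). For the other 3 pairs capture cannot be told apart from tagged cells. Among the 4, kidney lymphocytes rested on 3 members only, with an SD of 0.88 between control replicates. By the median difference of members, 2 of the 7 pairs stayed within 1 of control, the bound set beforehand against capture. The 2 were myeloid genes, in brain (-0.08) and liver (-0.99), but by the list medians the liver pair was lower by over 1 (3.13 against 4.38). Brain lymphocytes (-1.34, SD between control replicates 0.40) passed 1 by less than that spread. In brain and liver the lists of resident macrophages also stayed within 1 of control (microglia -0.02 in brain, Kupffer cells -0.66 in liver), so these cells stay open as a source there.

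RNA related to ribosomal RNA, which no comparison used, exceeded the level of the matching control group in several groups. Its mean share of RPKM was 88.4% in lysate and 77.2% in TRAP of enzymatic brain, 11.4% and 4.19% in kidney, and 60.7% and 41.6% in liver. In EIIa-Cre mice it was 8.45% in heart lysate, 1.33% in liver TRAP, 28.1% in lung lysate and 22.7% in lung TRAP.

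The counts were set against other splits of the same libraries. For comparisons of 3 with 3 libraries there are 10 splits, too few for a share under 0.05. The highest other split of Tek-Cre TRAP against lysate gave 0 genes in each tissue, against 10729, 6690, 8615, 7646 and 2661 for the real split in brain, heart, kidney, liver and lung. For EIIa-Cre it gave 1 in brain (real 2136), 0 in heart (1373), kidney (207) and liver (513), and 1446 in lung (1246), where 2 splits reached the real count. For LPS in TRAP it gave 303 in heart (6672) and 0 in brain (10947), kidney (8727), liver (8023) and lung (6485). For LPS in lysate it gave 2 in heart (3657), 1 in kidney (3358) and 0 in brain (2404), liver (4142) and lung (5021). For enzymatic dissociation it gave 0 throughout, against 9406, 5575 and 5256 in TRAP and 6963, 4749 and 4118 in lysate of brain, kidney and liver.

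Larger sets were compared over 100 splits, and the number of splits that reached a count includes the real one. These splits did not decide on chance for enrichment beyond the pull-down control, where 8 splits reached the real count in brain (2567, highest other 2678), 7 in heart (1092, 1337), 11 in kidney (2425, 2628), 8 in liver (2538, 2763) and 9 in lung (79, 1949). Nor did they decide on it for the LPS interaction in kidney (2 splits, 6647, highest other 8108), liver (2 splits, 6223, 7877), heart (6 splits, 2175, 4654) and lung (8 splits, 255, 5577). All but the real split of these kept the real grouping of 1 fraction and mixed the other, so that by construction the real group difference of that fraction entered the count. The highest other counts in lung, several times the real ones, were of this kind, which is a structure of the samples. The other splits that moved lysate and TRAP together gave 0, but with the real one they number 10, too few for a share under 0.05, and in heart, kidney, liver and lung, where every pair of equal number was correlated by over 0.1, they are the comparable ones. Only the real split reached the count for the LPS interaction in brain (9655, highest other 8934), where not every pair was correlated, and for the response across beds (13876, 7385). The same held for genes restricted to 1 bed in brain (267, 82), kidney (72, 0), liver (200, 82) and lung (21, 2), while in heart 3 splits did (45, 68). These splits do not decide on chance either. Those for LPS mixed treated with control libraries, so they did not set the counts against an equal response. Those for restricted genes kept the enriched lists of the real grouping of the same libraries, which favours the real split.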

How the results depend on the processing

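Tests without scaling, with a pseudocount of 0.1 and with carry-over subtracted were chosen after the result was seen, and the other alternatives were planned. A count was taken as kept when it stayed within 1.5 times the reported one. A test on counts (DESeq2 Wald or likelihood ratio), also planned, was not run, because no counts are used. Kept counts or medians were 44 of 45 with median-of-ratios factors (moved: enriched genes 135 in lung), 42 of 43 without the filter on low values (moved: blood 1), 43 of 43 with a pseudocount of 0.1, 2 of 2 with at least 500 estimated reads, 4 of 5 without the EIIa-Cre control (moved: genes restricted to 1 bed 67 in lung) and 9 of 10 with carry-over subtracted (moved: the LPS interaction 3328 in heart). With the replicate block 35 of 43 were kept, and the others were Tek-Cre TRAP 5846 in lung, EIIa-Cre TRAP 646 in kidney, 1033 in liver, 5225 in lung, enriched genes 423 in lung, genes restricted to 1 bed 103 in lung, the LPS interaction 2866 in lung and blood 598. Without scaling 28 of 43 were kept, and the others were Tek-Cre TRAP 1497 in lung, EIIa-Cre TRAP 8229 in heart, 1299 in kidney, 72 in lung, enriched genes 2474 in heart, 4583 in liver, 5 in lung, genes restricted to 1 bed 76 in heart, 1 in lung, LPS in lysate 5280 in kidney, the LPS interaction 1534 in lung, enzymatic TRAP 9099 in liver, enzymatic lysate 12632 in brain, 7178 in liver and blood 4341. The cause was not tested. The unreplicated medians were 3.80 (reported 3.91) for pan-endothelial genes after transplant, over 4 tissues, and 0.34 (reported 0.28) for platelet genes with median-of-ratios factors.

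Deviations of equal replicate number were also correlated in other sets, and every pair was over 0.1 in 2 of 26 sets of control with another group, 1 of 10 sets of TRAP of different tissues and in blood, so the paired values for restricted genes rest on weak pairing.

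The split into genes higher and lower moved by over 10 percentage points in some results (given as higher/lower, with the reported split in brackets). With median-of-ratios factors this held for Tek-Cre TRAP 1128/1872 (673/1988) in lung, EIIa-Cre TRAP 612/667 (395/851) in lung, the LPS interaction 1190/964 (860/1315) in heart, 103/153 (67/188) in lung, enzymatic TRAP 2628/4098 (1036/8370) in brain, 2019/2359 (1181/4075) in liver, enzymatic lysate 2710/2650 (2254/4709) in brain. Without scaling it held for Tek-Cre TRAP 8583/1386 (3107/3583) in heart, 6273/3248 (4385/4230) in kidney, 6861/2257 (4264/3382) in liver, 180/1317 (673/1988) in lung, EIIa-Cre TRAP 1881/738 (1099/1037) in brain, 8144/85 (785/588) in heart, 1189/110 (78/129) in kidney, 364/172 (295/218) in liver, 0/72 (395/851) in lung, LPS in TRAP 1932/6166 (3254/3418) in heart, 3674/5760 (4418/4309) in kidney, 2523/6565 (3652/4371) in liver, 1374/7299 (2819/3666) in lung, LPS in lysate 1045/1480 (1366/1038) in brain, 781/4281 (2183/1474) in heart, 1058/4222 (1999/1359) in kidney, 1158/4758 (2156/1986) in liver, 1775/4200 (2463/2558) in lung, the LPS interaction 95/1439 (67/188) in lung, enzymatic TRAP 2358/3426 (3193/2382) in kidney, 233/8866 (1181/4075) in liver, enzymatic lysate 116/12516 (2254/4709) in brain, 591/5589 (2138/2611) in kidney, 448/6730 (1909/2209) in liver, blood 4282/59 (23/122).

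Leaving out 1 library at a time gave Tek-Cre TRAP 9674 to 10334 in brain, 5687 to 6600 in heart, 7525 to 8187 in kidney, 6262 to 7356 in liver, 1858 to 2348 in lung, EIIa-Cre TRAP 1251 to 1806 in brain, 570 to 926 in heart, 68 to 106 in kidney, 100 to 231 in liver, 215 to 1805 in lung, enriched genes 2007 to 2614 in brain, 938 to 1183 in heart, 1736 to 2466 in kidney, 1640 to 2576 in liver, 16 to 161 in lung, genes restricted to 1 bed 198 to 270 in brain, 42 to 46 in heart, 43 to 73 in kidney, 131 to 212 in liver, 9 to 22 in lung, LPS in TRAP 10187 to 10426 in brain, 5656 to 6352 in heart, 7836 to 8456 in kidney, 6874 to 7656 in liver, 5399 to 6882 in lung, LPS in lysate 1272 to 2420 in brain, 2772 to 3122 in heart, 2478 to 3117 in kidney, 3222 to 3939 in liver, 3437 to 5518 in lung, the LPS interaction 9013 to 9403 in brain, 1444 to 2596 in heart, 5922 to 6573 in kidney, 5171 to 6096 in liver, 66 to 385 in lung, enzymatic TRAP 6971 to 9174 in brain, 4644 to 5330 in kidney, 3566 to 5353 in liver, enzymatic lysate 6049 to 6665 in brain, 3630 to 4250 in kidney, 2787 to 4033 in liver, blood 83 to 164 and the response across beds 13018 to 14070. Where this left 1 library in a blood group, it was assumed to vary like the other group. Of simulated 2-fold changes, 1.49% were called in blood (n = 2), whose lysates had 5.6 to 7.71 M reads, so small differences there may have been missed.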

Other observations

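In this part all tests of gene lists were planned. Several lists were not described so far. Genes of the VEGF and angiopoietin pathway were higher in Tek-Cre TRAP than in lysate of brain (9 of 10), heart (10 of 10), kidney (10 of 10), liver (8 of 8) and lung (4 of 10, 8 with replicates as blocks). After LPS they fell in TRAP of brain (8 of 10), heart (7 of 10), kidney (9 of 10), liver (7 of 8) and lung (8 of 10). Tek, the angiopoietin receptor, fell by 4.54 ± 0.16 in brain and 3.53 ± 0.41 in lung, while Angpt2, its context-dependent ligand, rose by 1.25 ± 0.26 in brain, 1.06 ± 0.20 in kidney and 1.66 ± 0.51 in lung. Junction genes fell in TRAP of brain (7 of 9, with 1 higher), heart (5 of 7, 1 higher) and kidney (6 of 9, 3 higher), with Cldn5 in brain at -4.42 ± 0.44. In kidney, Ocln and Cgn, also expressed by epithelium, were higher by 2.25 and 2.22.

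Hemostasis genes moved both ways in LPS TRAP. In lung 6 rose and 2 (3 adjusted over the list alone) of 10 fell, and in kidney 3 rose and 6 of 11 fell. Thbd, the anticoagulant thrombomodulin, fell in lung from 454 ± 84 to 10.5 ± 5.41 RPKM. F3, tissue factor, rose in TRAP by 3.85 ± 0.19 in brain and 2.91 ± 0.20 in kidney. In brain it differed in lysate by 0.46 ± 0.19 and stood at -3.06 against lysate in control TRAP and at 0.32 in LPS TRAP, beside neuronal markers at 10.7% and 71.8% of lysate. Genes of the NF-kB pathway and its feedback rose in heart (11 of 11), kidney (10 of 11), liver (9 of 11) and lung (11 of 11), and in brain 6 rose and 2 of 11 fell. Tnfaip3, a feedback inhibitor, rose by 4.90 ± 0.21 in heart. Heat-shock genes rose in 9 of 10 members in lung TRAP (median 1.55), with Hsp90aa1 up by 2.83 ± 0.44. Immediate-early genes rose in lung lysate (15 of 17, median 2.10), with Junb up by 4.67 ± 0.63, and fell in TRAP of enzymatic brain (13 of 19, with 2 higher), where Btg2 changed by -4.21 ± 0.36 and Jun by 2.90 ± 0.30, beside a median of all genes of -1.17.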
